A study of Homo sapiens with 2 samples.

How the data were processed

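Total RNA of WERI retinoblastoma cells was measured on 2 two-colour arrays, per the labels, which name a let-7 transfection and, for the second array, an exchange of the fluorophores. Channel 1 carried Cy5 and channel 2 Cy3 on array 1, and the reverse on array 2, per the labels. Both channels have the same source in the labels, so the channel that held RNA of let-7 transfected cells is not settled. The protocol in the labels describes reagent-based RNA extraction and labelled cDNA for the messenger RNA arrays.

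The authors deposited 1 value per probe and array, treated here as a score that behaves like a log ratio. Background correction, normalization, log base, centring and direction are not given in the sources used here. The deposited scores ranged from -0.331 to 0.294 on array 1 and from -0.691 to 0.327 on array 2, and 87.1% and 76.5% of them lay within 0.05 of 0. No channel intensities were used here, so signal over background is unknown, dim probes could not be left out, and gene lists could not be matched on expression. Compression of ratios by the upstream processing would shrink every value reported. The table held 0 columns of other samples.

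The platform annotation named 1 gene for 23105 probes, several for 0 and none for 18570, which are called unnamed. All 23105 gene identifiers matched the reference gene table, which changed 0 symbols. Probes of a gene were averaged per array, giving 15741 genes, 10354 with 1 probe and 5387 with several. Genes of the Y chromosome and XIST are not printed or drawn.

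The comparisons were fixed before the data were examined. Both arrays are 1 comparison with exchanged dyes and count as 1 replicate, so the main results come from no test across samples. limma over the 2 arrays was an alternative, given as counts, and its p-values measure only the spread between arrays of 1 comparison. The orientation rule turned the sign of array 2 if the correlation across probes was negative, which it was. The size rule asked for the same sign in both arrays and at least 1.5-fold in each, and was planned for log2 ratios. Since the unit differed from that plan, 1.5-fold was read as 0.176 on a base 10 scale, with base 2 (0.585) and base e (0.405) as alternatives. The as-deposited orientation, a threshold of 0.05 deposited units, random lists matched on the mean of the other orientation in 50 bins, and the counts in the outer 1% of genes were added after the data were seen. Values in the outer tail of random lists describe these arrays and are not p-values, and with 18 lists in 2 orientations some would lie there without any relation.

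Gene lists were fixed before the data were examined: reported let-7 targets, G1/S and DNA replication, G2/M and mitosis, cone, rod, Muller glia, other retinal neurons, retinal pigment epithelium and stroma, retinoblastoma oncogenes, interferon response, microRNA machinery, p53 and DNA damage, stress and unfolded protein response, cholesterol synthesis, ribosomal proteins, mitochondrial respiration, glycolysis and housekeeping. The list named retinoblastoma oncogenes also held genes that are not oncogenes, such as CDKN1B, CDKN2A, RBL1, RBL2 and TFF1. Each list's median was placed among 10000 random lists of the same size, matched on the number of probes per gene. The target list shares 6 measured genes with the microRNA machinery, 2 with G1/S, 2 with retinal pigment epithelium and stroma, and 1 each with the cone, oncogene, p53 and cholesterol lists.

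Genes were named by a rule fixed before the data were examined: up to 12 in each direction past the size rule by the smaller of the sizes on the 2 arrays, 6 let-7 targets, up to 4 of each other list by the same measure, and a fixed set of HMGA2, LIN28B, DICER1, CDC25A, NRAS, MYC, MYCN, CDK6 and CCND2, besides an item that is not reported here. The rule was applied in both orientations, with the added threshold of 0.05 in place of 1.5-fold where fewer passed. Genes named beyond the rule are said to have been chosen after their values were seen.

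Alternatives were median centring of each array, a common scale, the probe whose arrays differ least, leaving out probes whose arrays differ by over 1 log2 unit (read from base 10), each array alone, other fold thresholds, the mean of both arrays, limma with Benjamini-Hochberg adjustment, the mean of a list, and random lists without matching. A planned search for let-7 seed matches in 3' UTRs was not run, since no transcript sequence was used here. The steps were tested on simulated data over 15741 genes in the dye-turned orientation with changed genes added. The 1.5-fold rule found 0% of genes changed by 0.05 or 0.1 units, 62% at 0.2 and 100% at 0.3, and 0 of 15541 unchanged genes. The 0.05 rule found 24%, 96%, 100% and 100%, and 4 unchanged genes. limma found 50% at 0.05 and 100% at the larger sizes, and 7 unchanged genes. The simulated noise was independent between the arrays and held no dye effect of single genes. These false calls therefore do not cover a dye effect that gives both arrays 1 sign after turning. Of 200 simulated lists of 90 genes without a shift, 3 fell in the lowest and 7 in the highest 2.5% of random lists. Analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.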

Results

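RNA from WERI cells, an established human retinoblastoma line, was compared after transfection with let-7, a microRNA family that represses messages carrying its seed match. The comparison was hybridised to 2 two-colour expression arrays with the Cy5 and Cy3 dyes exchanged on the second. Each array gave a log-ratio-like score for 41675 probes, of which 23105 carried a gene name and stood for 15741 genes. The scores had a median of -0.003 and an SD of 0.0345 on array 1, and a median of 0.0068 and an SD of 0.0453 on array 2. Both arrays were counted as 1 replicate, so every value below lacks a check against an independent transfection, and the number of arrays limits the precision. The labels do not say which channel held the let-7 RNA, and the log base, centring and direction of the scores stay unknown. Signs are therefore those of the deposited columns, not let-7 over control, and all signs exchange if the ratio was taken the other way round.

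The question the design poses is which transcripts differed in abundance when let-7 was added. HMGA2, a chromatin protein gene and long-studied let-7 target, scored -0.110 on array 1 and -0.0512 on array 2 as deposited, averaged over 2 probes. The 90 measured genes of a list of reported let-7 targets had a median of -0.0288 on array 1, against -0.0047 for all genes, and of 0.0132 on array 2, against 0.012 for all genes. DICER1, which encodes the nuclease that releases mature microRNAs, scored -0.0957 and 0.0107. CDC25A, a phosphatase gene of the G1 to S transition, scored -0.0367 and 0.0098. MYCN, the neuroblastoma and retinoblastoma oncogene, took opposite signs of about equal size, -0.118 and 0.110.

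Across all 41675 probes the deposited columns of the 2 arrays were inversely related, with a Pearson r of -0.563 and a Spearman rho of -0.540. These are correlations across probes, which are not independent replicates. By the rule set for a negative correlation, the sign of array 2 was turned before averaging, and this gave the main values, called the dye-turned mean here. A negative correlation does not by itself set the orientation. If the columns already share the direction of let-7, a dye effect larger than the response would give it too. The dye-turned mean would then mostly hold that dye effect. The mean of both columns with no sign turned, called the as-deposited mean, was added after the data were seen, because HMGA2 and some other reported targets carried 1 sign in both columns. Of the 90 targets, 20 share a sign as deposited, 15 below 0 and 5 above, while 68 share a sign once array 2 is turned, 56 below and 12 above. Over all 15741 genes, 11.7% lay below 0 in both arrays and 16.7% above as deposited. Once array 2 is turned the shares were 44.9% and 26.4%, so the contrast between orientations is not particular to the targets. The dye-turned mean had an SD of 0.0354 over probes and the as-deposited mean an SD of 0.0193. In the 4210 genes with exactly 2 probes, the probes of a gene correlated at r = 0.302 in the dye-turned mean and 0.271 in the as-deposited mean.

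**Figure D1:**
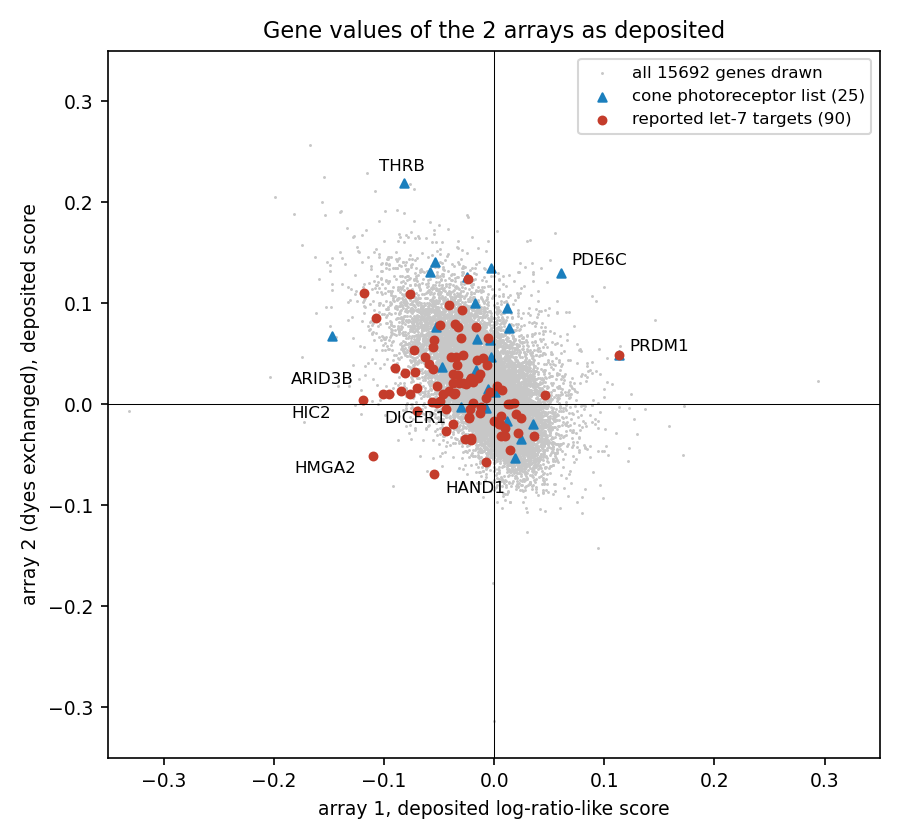
Deposited score of each gene on array 1 (x axis) against array 2 (y axis), in deposited units, with all drawn genes in grey, reported let-7 targets as red circles and cone photoreceptor genes as blue triangles. The grey cloud slopes downward, and HMGA2 (-0.110 and -0.0512) lies in the lower left quadrant, away from it.

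In the dye-turned mean, IARS1, which encodes a cytoplasmic tRNA synthetase for isoleucine, had a value of -0.202, and DEK, a chromatin protein gene often gained in retinoblastoma, had a value of -0.185. These were the 2 genes past 1.5-fold in each array when the scores were read as base 10 logarithms, both below 0, and 0 genes above 0 passed. At 0.05 deposited units in each array, a threshold chosen after the data were seen, 1078 genes lay below 0 and 44 above. By the smaller of the sizes on the 2 arrays, the 12 lowest also held MATR3, a nuclear matrix RNA-binding protein gene (-0.212), NUDT5 (-0.178), UCK2, a uridine-cytidine kinase gene (-0.166), NFYA, a CCAAT-box factor gene (-0.146), TTK, a spindle checkpoint kinase gene (-0.147), DHRS7 (-0.145), PCNX4 (-0.170), SNURF (-0.165) and the zinc finger genes ZNF85 (-0.190) and ZNF676 (-0.154). The 12 highest by that measure were H4C3, a histone H4 gene (0.118), CPNE5 (0.0959), PLAUR, the urokinase receptor gene (0.094), TECPR1 (0.088), HOXD10 (0.0858), CDC27, an anaphase-promoting complex gene (0.0856), MAPK11 (0.0835), NPY, the neuropeptide Y gene (0.0792), HES4 (0.0781), BACE2 (0.0738), PAOX (0.0688) and MRPS34 (0.0673). Over all 15741 genes, 44.9% lay below 0 in both arrays and 26.4% above 0 in both. Read as base 2, 0 genes passed 1.5-fold, and none could, since array 1 ranged only from -0.331 to 0.294. limma over the 2 arrays gave 1427 genes at an adjusted p under 0.05, which measures only the spread between arrays of 1 comparison.

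Gene lists for functions of most growing cells had medians below 0 in the dye-turned mean, and their signal on the arrays is not known. The 64 ribosomal protein genes had a median of -0.0359, with 45 below 0 in both arrays and 6 above, and RPL36 (-0.115), RPL31 (-0.112), RPL17 (-0.0964) and RPS3A (-0.0883) were among them. Of 10000 random lists with the same numbers of probes per gene, 0 had a median at or below it. The 17 housekeeping genes had a median of -0.0435 (26 of 10000 random lists at or below), from EEF1A1, a translation elongation factor gene (-0.107), YWHAZ (-0.0731), GUSB (-0.0718) and PSMB2 (-0.0676). The 30 genes of mitochondrial respiration had a median of -0.0365 (2 random lists), with ATP5F1B at -0.142, COX6A1 at -0.102, NDUFA9 at -0.0892 and CYC1 at -0.0636. The 25 glycolysis genes had a median of -0.0261 (295 random lists), with LDHA at -0.115, LDHB at -0.0776, ENO2 at -0.0558 and, on the other side, GAPDH at 0.0667. With the probe whose arrays differ least in place of the mean of probes, the glycolysis median was -0.0162 (1706 random lists), and on array 1 alone -0.0128 (1644). The 20 genes of cholesterol synthesis had a median of -0.0418 (6 random lists), with SQLE at -0.0967, EBP at -0.0861, NSDHL at -0.0682 and SC5D at -0.0567, and on array 2 alone 462 random lists lay at or below it.

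Cell division genes and the microRNA machinery lay on the same side of the dye-turned mean. The 47 genes of G1/S and DNA replication had a median of -0.0383, with 34 below 0 in both arrays, and 0 of 10000 random lists reached it. TYMS, the thymidylate synthase gene (-0.160), GMNN, the geminin gene (-0.0979), MCM6 (-0.0833) and CHEK1 (-0.0829) had the largest values in both arrays. The 45 genes of G2/M and mitosis had a median of -0.0448 (0 random lists), with TTK, ANLN (-0.0951), the mitotic kinesin gene KIF11 (-0.0844) and CCNA2 (-0.0699). The 33 genes of the microRNA machinery had a median of -0.0449 (1 random list), with 28 below 0 in both arrays, among them MOV10 (-0.0942), TNRC6C (-0.0868), DDX5 (-0.0821) and HNRNPA1 (-0.0627). The 90 reported let-7 targets had a median of -0.0254 (7 random lists, and 0 of 10000 lists matched on the as-deposited mean), closer to 0 than the lists just named, with MYCN (-0.114), GEMIN7 (-0.0963), BACH1 (-0.0928), NME4 (-0.0635), SURF4 (-0.0589) and BZW1 (-0.056). Of the lists matched on the as-deposited mean, 0 lay at or below G1/S, 1 at or below G2/M, 1 for the microRNA machinery, 0 for ribosomal proteins, 8 for housekeeping, 4 for respiration, 254 for glycolysis and 9 for cholesterol synthesis. With array 2 alone the targets' median was -0.0132, and 6510 of 10000 random lists lay at or below it. With array 1 alone the G2/M median was -0.0186 (66 random lists) and that of the microRNA machinery -0.028 (14). On that array the order turned, as the targets' median of -0.0288 lay further from 0 than these and that of G1/S (-0.0272).

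The medians for pigment epithelium and stroma, rods and other retinal neurons lay above 0 in the dye-turned mean, unlike those for cone genes. The 23 genes of retinal pigment epithelium and stroma had a median of 0.0132 (9996 of 10000 random lists at or below), with CD68, a macrophage gene (0.0468), RGR (0.0455), TYRP1, a pigment gene (0.0332) and, below 0, LUM (-0.0494). The 21 rod photoreceptor genes had a median of 0.0085 (9804 lists), with REEP6 (0.0436), FSCN2 (0.033), CNGB1 (0.0235) and PDE6A (-0.0361). The 30 genes of other retinal neurons had a median of 0.00416 (9354 lists) and held STMN2 (-0.102), NEFL (-0.0731), NEFM (0.0565) and LHX1 (0.0336). The 17 Muller glia genes had a median of 0.0003 (8650 lists), with VIM, the vimentin gene (-0.108), NES (-0.0389), SOX9 (0.0323) and TF (0.0266). The 42 interferon response genes had a median of 0.00318 (9642 lists), with BST2 (-0.0673), USP18 (-0.0512), IFIT5 (-0.0485) and IFITM3 (0.0519), and the 30 stress genes had a median of -0.00928 (4390 lists), with the chaperone genes HSPA8 (-0.0928), HSP90B1 (-0.0789), HSPA5 (-0.0768) and DNAJB1 (-0.0708). The 26 p53 and DNA damage genes had a median of -0.0286 (91 lists), with CCNG1 (-0.137), AEN (-0.117), RRM2B (-0.0679) and TIGAR (-0.0615). The 19 genes of the retinoblastoma oncogene list had a median of -0.0246 (655 lists), with DEK, SKP2 (-0.0687) and MDM4 (-0.0462). The 25 cone photoreceptor genes had a median of -0.0337 (11 lists). They held THRB, the thyroid hormone receptor gene of cone development (-0.150), RXRG (-0.107), CNGA3 (-0.0973) and RCVRN (-0.0946). Of the lists matched on the as-deposited mean, 9975 lay at or below pigment epithelium and stroma, 9824 at or below rod, 9682 for other retinal neurons, 8486 for Muller glia, 9935 for interferon, 5517 for stress, 349 for p53, 2273 for oncogenes and 700 for cone genes. With the probe whose arrays differ least, the pigment epithelium and stroma median was 0.0029 (9142 lists), the rod median 0.00235 (8576) and the Muller glia median -0.0107 (3882). Array 1 alone put the cone median at -0.0054 (3362 lists), the oncogene median at -0.0082 (4023), the p53 median at -0.0153 (658) and that of other retinal neurons at -0.0024 (5608), and array 2 alone put the rod median at 0 (8618) and the interferon median at -0.00975 (5491).

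In the as-deposited mean, reported let-7 targets lay on the negative side. Their median was -0.00693, with 15 of 90 below 0 in both arrays and 5 above, and 0 of 10000 random lists lay at or below it. Over all genes 11.7% lay below 0 in both arrays and 16.7% above. Random lists whose genes had the same dye-turned means, in 50 bins, had a median of 0.0058, with the middle 95% from 0.00186 to 0.00971, and 0 of these lay at or below the targets either. HMGA2 had a mean of -0.0804, a ratio of 0.831 if the scores are base 10 logarithms and 0.946 if they are base 2. Of the 90 targets, 7 were among the 1% of genes with the lowest means, where 0.9 would fall with no relation, and they are named here after their values were seen. They were HMGA2, HAND1, a transcription factor gene of heart development (-0.0618), HIC2 (-0.0574), ARID3B (-0.0455), DICER1 (-0.0425), RAB40C, a small GTPase gene (-0.0383), and CDC34, a ubiquitin-conjugating enzyme gene (-0.0358). These 7 were left out of the list, and as many lowest members out of each list matched on the dye-turned mean, after the data were seen. The other 83 had a median of -0.00395, and 0 of 10000 matched lists lay at or below it. On array 2 alone HIC2 (0.0047), ARID3B (0.0098), DICER1 (0.0107) and CDC34 (0.0132) lay above 0. Array 2 alone did not separate the list from other genes (median 0.0132, 3492 of 10000 random lists at or below). In the dye-turned mean 1 of the 90 targets was among the lowest 1%, against 0.9 with no relation. The lowest 1% of the as-deposited mean also held 3 of 30 stress genes (0.3 with no relation). It held 2 of 19 genes of the retinoblastoma oncogene list (0.19), the p27 inhibitor gene CDKN1B and the trefoil peptide gene TFF1. The other lists held 0 or 1 there.

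Other reported targets were spread on both sides of 0. YOD1, a deubiquitinase gene, scored -0.0436 and -0.0262 on the arrays, HMGA1, the relative of HMGA2, -0.0268 and -0.0341, NME6 -0.0209 and -0.0338, and E2F2 -0.0377 and -0.0196. PRDM1, a repressor gene of photoreceptor fate decisions that stands in both the target and the cone lists, scored 0.114 and 0.0485. The oncogene MYC had an as-deposited mean of 0.00133, CDK6, a G1 kinase gene, 0.0159, CCND2, a D-type cyclin gene, -0.00233, and LIN28B, which encodes a repressor of let-7 maturation, 0.00548. TARBP2, which encodes a partner of Dicer, had a mean of -0.032. NRAS was not analysed here.

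**Figure D2:**
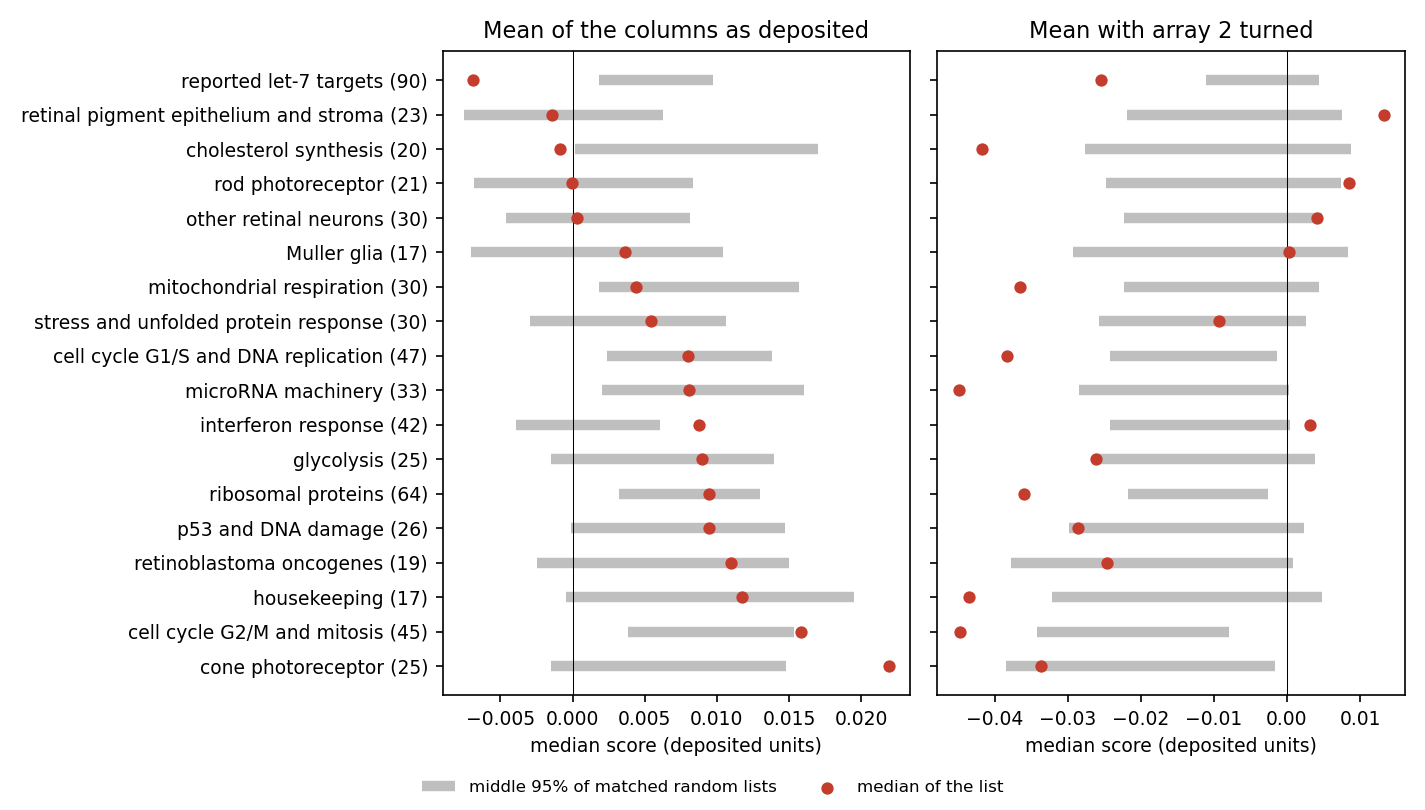
Median score of each of the 18 gene lists (red points, deposited units, number of measured genes in brackets) in the as-deposited mean (left) and the dye-turned mean (right), with the middle 95% of 10000 random lists matched on the other mean (grey bars). On the left the let-7 targets (-0.00693, but 0.0132 on array 2 alone) lie below their grey bar and the cone photoreceptor genes (0.0219, but -0.0054 on array 1 alone) above theirs.

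At 0.05 deposited units in both arrays as deposited, 6 genes lay below 0 and 31 above, and 0 genes passed 1.5-fold read as base 10. The 6 were HMGA2, HAND1, FOSB, an immediate early transcription factor gene (-0.0916 and -0.0812), KCNJ11, a potassium channel gene (-0.061 and -0.0659), ENDOV (-0.0553 and -0.0531) and CC2D2B (-0.0672 and -0.0508). By the smaller of the sizes on the 2 arrays, the 12 highest were PCP2, a retinal bipolar and Purkinje cell gene (mean 0.115), POMK (0.108), SULF1, an extracellular sulfatase gene (0.0982), PHACTR2 (0.097), PDE6C, the cone phosphodiesterase gene (0.0952), NRGN, the neurogranin gene (0.0798), DDIT4L (0.0784), CAPNS1 (0.0751), SPP1, the osteopontin gene (0.0676), SPRYD3 (0.0672), ATN1 (0.0651) and STRN4 (0.0636). limma over both arrays gave 0 genes at an adjusted p under 0.05 and 43 at an unadjusted p under 0.05, of which 38 lay above 0.

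SPP1 and IGF2BP1, singled out after their values were seen, carried many probes. SPP1, a secreted matrix protein gene, lay above 0 in the as-deposited mean for 10 of 10 probes, with a mean of 0.0676 and an SD of 0.0306 over probes. IGF2BP1, an RNA-binding protein gene from the list of reported let-7 targets, lay below 0 for 11 of 11 probes, with a mean of -0.0254 and an SD of 0.0115. In the dye-turned mean 10 of the 11 IGF2BP1 probes also lay below 0, with a mean of -0.0264, so this gene does not separate the orientations. On array 2 alone 7 of the 11 IGF2BP1 probes lay above 0. Whether the probes of a gene share a sequence is not given in the sources used here, and they are not replicates of the cells.

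**Figure D3:**
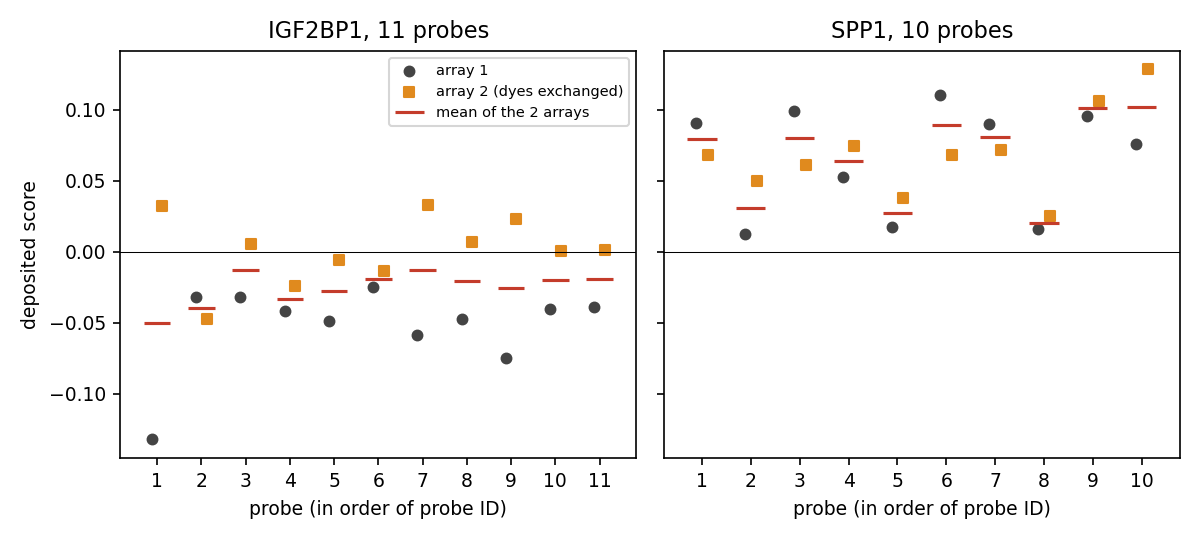
Deposited score (y axis, deposited units) of each probe (x axis) of IGF2BP1 (left, 11 probes) and SPP1 (right, 10 probes) on array 1 (circles) and array 2 (squares), with the mean of both arrays as a red bar. All red bars lie below 0 for IGF2BP1 and above 0 for SPP1.

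Cone photoreceptor and mitotic genes lay on the positive side of the as-deposited mean. The 25 cone genes had a median of 0.0219, and 10000 of 10000 random lists and 9997 of those matched on the dye-turned mean lay at or below it. Of the 25 cone genes, 5 lay above 0 in both arrays and 2 below, beside 16.7% and 11.7% of all genes. The highest 1% of all genes held 4 of the 25, and the lowest 1% held 1, RXRG (mean -0.0401). PDE6C scored 0.0603 and 0.130 on the arrays, PRDM1 0.114 and 0.0485, GNB3, a cone transducin gene, 0.0139 and 0.0752, and IMPG2 0.0116 and 0.0949. The 45 genes of G2/M and mitosis had a median of 0.0159, with 10000 random lists and 9835 matched lists at or below, from MAD2L1, a spindle checkpoint gene (0.0229 and 0.131), SGO1, the cohesin protector gene (0.0398 and 0.0891), CCNB2 (0.0348 and 0.0699) and PTTG1, the securin gene (0.0297 and 0.0532). Of the 45 G2/M genes, 10 lay above 0 in both arrays and 1 below. On array 1 alone the medians were below 0 for both lists, -0.0054 for cone genes and -0.0186 for G2/M genes. Leaving out the 4 highest members of the cone list and of each matched list, a step added after the data were seen, gave a cone median of 0.00895 over 21 genes, with 9339 matched lists at or below.

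Among the remaining lists of the as-deposited mean, interferon response and cholesterol synthesis genes lay furthest from their matched lists. The 42 interferon response genes had a median of 0.00874 (9661 of 10000 random lists and 9983 of the matched lists at or below), with 15 above 0 in both arrays and 5 below. Over all genes 16.7% lay above 0 in both arrays and 11.7% below. IFI44L scored 0.0505 and 0.0721, the antigen presentation genes TAP1 0.0824 and 0.0288 and B2M 0.0585 and 0.0298, and ISG20 0.0264 and 0.0415. With the probe whose arrays differ least, the interferon median was 0.00435 (7109 random lists), and on array 2 alone it was 0.00975 (4528). The 20 cholesterol synthesis genes had a median of -0.00085 (1654 random lists, 133 matched lists), and the sterol regulators SREBF1 (-0.024 and -0.0375) and SREBF2 (-0.0126 and -0.0188) and DHCR7 (-0.0227 and -0.0255) lay below 0 in both arrays, while MSMO1 lay above (0.0252 and 0.0389). With both arrays set to 1 scale, the cholesterol median was -0.0135 (0 random lists), below that of the let-7 targets on that scale (-0.00962), and the list had medians of -0.0353 on array 1 and 0.0325 on array 2.

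The other lists of the as-deposited mean lay inside the middle 95% of lists matched on the dye-turned mean. Their medians, with the number of the 10000 matched lists at or below, were 0.008 for G1/S and DNA replication (5013), 0.00943 for ribosomal proteins (7028), 0.0117 for housekeeping genes (7062), 0.00443 for mitochondrial respiration (1100) and 0.00895 for glycolysis (7824). Setting both arrays to 1 scale put the housekeeping (-0.000843), respiration (-0.00439) and glycolysis (-0.00115) medians below 0. The medians were 0.00805 for the microRNA machinery (4286), 0.00943 for p53 and DNA damage (7329), 0.00546 for stress (6905) and 0.011 for the retinoblastoma oncogene list (8625). Within these, HMOX1, the heme oxygenase gene, scored 0.0771 and 0.0537, PHLDA3, a p53 target gene, 0.0387 and 0.0869, GADD45A 0.0108 and 0.103, TFF1, a trefoil peptide gene, -0.0401 and -0.04, CDKN1B, the p27 inhibitor gene, -0.0447 and -0.0282, CDKN2A 0.051 and 0.0281, and MCM2 0.0533 and 0.0207. The rod list had a median of -2.5e-05 (4533), Muller glia 0.00365 (7167), other retinal neurons 0.0003 (3349) and retinal pigment epithelium and stroma -0.0014 (4583). SAG, the rod arrestin gene, nevertheless scored 0.114 and 0.0581, and PRKCA, a bipolar cell kinase gene, 0.0216 and 0.0938. On array 1 and array 2 alone the medians of Muller glia (-0.00545 and -0.00567) and other retinal neurons (-0.0024 and -0.00488) lay below 0.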

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

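The counts in this part were chosen after the data were seen. Probes without a gene name took no part in the comparisons of genes. In the dye-turned mean, 7 of the 18570 unnamed probes passed 1.5-fold read as base 10 in both arrays, all below 0, beside 6 of the 23105 named probes. In the as-deposited columns, 76 unnamed probes passed 0.05 in both arrays, 57 below 0 and 19 above, while the named probes split the other way, with 11 below and 62 above. PROBE37950 (-0.153 and -0.167) and PROBE38382 (-0.124 and -0.136) were the lowest of these in both arrays and PROBE30294 (0.099 and 0.0814) and PROBE1051 (0.0702 and 0.0737) the highest. What these probes measure was not analysed here.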

How the results depend on the processing

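Alternatives on the as-deposited columns, other log bases, the 0.05 threshold, the count of probes, lists matched on the other mean and lists without their lowest or shared members were chosen after the data were seen; the rest were planned. Signal over background is unknown and limits every value. The main count was 2 genes past 1.5-fold in the dye-turned mean. Centring, a common scale and leaving out discordant probes each gave 2. The probe whose arrays differ least gave 4, a lower fold threshold 90, 2-fold 0, the mean of both arrays 5, limma 1427 (70 above 0), base 2 0, base e 0, the columns as deposited 0, 0.05 units 1122, and probes in place of genes 13. Single arrays gave 5 to 24. Past 0.05 in the as-deposited columns, the count above 0 was 31, with 49 by the least differing probe, 0 by limma and 364 to 3309 on single arrays. The count below 0 was 6, with 0 by limma and 570 to 1502 on single arrays. Looser thresholds and single arrays pass more genes by construction. No score on array 1 reached the base 2 or base e threshold, so those counts of 0 were fixed in advance. The least differing probe is picked for agreement of the arrays in the orientation scored, which favours passing a rule on both arrays. The cause of the other differences was not tested.

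The let-7 targets' median of -0.0254 in the dye-turned mean became -0.00693 with the columns as deposited, and lay between -0.0288 and -0.0132 on single arrays. In the as-deposited mean it was -0.00693, and ran from -0.0288 on array 1 to 0.0132 on array 2. Centring, scale, probe choice, the mean of members and leaving out shared members moved it by less than the SD between arrays. As-deposited medians had opposite signs on array 1 and array 2 in 14 of the 18 lists, the targets included, among them G2/M (-0.0186 and 0.0654), cone (-0.0054 and 0.0636) and ribosomal protein genes (-0.029 and 0.0443), and the cause was not tested. Of the other values of lists and named genes, 106 moved by more than the SD between arrays and 1540 did not, over centring, scale and probe choices. Where the arrays take opposite signs that SD is large, so the tally is a weak check of as-deposited values, the targets included. On a common scale the as-deposited cholesterol median went from -0.00085 to -0.0135 and the housekeeping median from 0.0117 to -0.000843. Both counted as not moved. Single arrays are not in that tally: for a gene they lie within that SD of its mean by construction, and for lists they also moved some medians past it. No paired analysis was possible because the arrays are 1 comparison. The search for seed matches in 3' UTRs was not run.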

Other observations

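The tests in this part were all chosen after the values they bear on had been seen, on lists fixed before. Of 68 genes with 8 or more probes each, IGF2BP1 was the 1 with all probes below 0 in the as-deposited mean, and 14 had all probes above 0. After SPP1, which had the highest mean of these, came the mitotic kinesin gene KIF20A (0.0443), the DNA repair gene SMC6 (0.0404), the kinetochore genes CENPQ (0.0367), SPDL1 (0.0352) and KNTC1 (0.0206), the chromatin assembly gene CHAF1B (0.0331), RAD54B (0.0297), EXO1 (0.028), DTL (0.0252) and PIMREG (0.0244). DNTTIP2 (0.0291), the cell death gene PMAIP1 (0.0268) and LOXL2 (0.0161) made up the rest, and how many of the 68 genes share these functions was not counted. On array 1 alone 12 of the 14 had most of their probes below 0, and SPP1 and CHAF1B had most above. In the dye-turned mean all probes lay below 0 in 29 of the 68 genes and above 0 in 2.

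The first pattern is the place of the reported let-7 targets below 0 in the as-deposited mean. A dye effect that follows the dye-turned mean would put random lists matched on that mean as low, and 0 of 10000 were. That matching cannot address a dye effect held by the as-deposited mean itself, which is possible if the dye-turned orientation is right. Whether the dye-turned mean instead holds the let-7 response stays open. There too, 0 of 10000 lists matched on the as-deposited mean lay as low as the targets. That low count was not particular to the targets: it was 0 for ribosomal proteins, 0 for G1/S and 8 for housekeeping genes. It was in the middle for stress genes (5517) and high for rod genes (9824). As deposited, the matched counts were 7028 for ribosomal proteins, 5013 for G1/S and 7062 for housekeeping, but 133 for cholesterol synthesis. The targets' count in the dye-turned mean therefore cannot be read as a let-7 response, and the matched lists do not set the orientation. An effect of array 1 alone, technical or not, also stays open, because a shift on 1 array lowers both means and on array 2 alone 3492 random lists lay at or below the targets. A hypothesis is that the as-deposited columns share the direction of let-7 over control and may hold repression of targets such as HMGA2, which lay below 0 on both arrays, but the orientation was chosen from such genes and no test here sets it.

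The second pattern is the place of the cone photoreceptor genes above 0 in the as-deposited mean. Matching on the dye-turned mean cannot address a dye effect held by the as-deposited mean itself. It argues only against a dye effect that follows the dye-turned mean, since 9997 of 10000 matched lists lay at or below the list. Whether only its highest members, PDE6C, PRDM1, THRB (-0.0813 on array 1 and 0.219 on array 2) and PDE6H, carry it stays open. With 4 members left out of the list and of each matched list, 9339 lay at or below the median of 0.00895 of the other 21 genes. That count is neither in the middle of these lists nor in their outer 2.5%. An effect of array 2 alone stays open too, since on array 1 alone the median was -0.0054 and 3362 random lists lay at or below it. A hypothesis is that, in that same orientation, let-7 may be followed by more message of a few photoreceptor genes, but no test here separates that from chance among 18 lists.

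The third pattern is the place of broadly expressed genes below 0 in the dye-turned mean. Dye bias that follows the signal of a probe could give it, as the ribosomal protein median of -0.0359 and the housekeeping, respiration and glycolysis medians share a sign, but without channel intensities that bias could not be measured. A response to the transfection was set against it through the let-7 targets, whose median lay 0.0181 above that of the housekeeping genes. Since neither the sign of let-7 over control nor expression levels are known, dye bias and a response to the transfection cannot be told apart for these genes.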
